A study of Mus musculus with 12 samples.

How the data were processed

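Transcript levels were measured in 12 single blastomeres, the 2 cells of each of 6 split 2-cell embryos of CF-1 mice collected 36 h post coitus. The labels place 3 embryos in each of 2 experiments, named pairs D, I and L in experiment 1 and pairs D, G and H in experiment 2, and number the cells of an embryo 1 and 2. The labels do not say what these numbers stand for, nor how the cells were told apart. RNA of each cell was amplified in 2 rounds, labelled and hybridised to an Agilent whole mouse genome array with 43379 non-control spots for 41174 probes.

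The scanner files hold intensity values that the authors extracted with Agilent Feature Extraction 9.1.3.1, per the file headers. The labels name Cy3 for every sample. The files show otherwise: the arrays of experiment 1 were scanned in 2 channels, and the signal sits in Cy5, where 22.1 to 41.7% of the non-control spots were well above background, while 68 to 160 spots were so in Cy3. The arrays of experiment 2 were scanned in Cy3 alone. The deposited value table holds intensity as well: it equals the processed signal of these channels divided by 1 constant per array, on a linear scale, with low values raised to a floor. Experiment, dye, scan protocol and slide therefore coincide, and no fit can tell them apart. Each slide held cells of 1 experiment, twins shared a slide, and 2 of the 4 slides held 2 embryos.

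Outlier spots were left out, spots of the same probe were averaged, and processed signals of the channel that held the RNA were divided by the 75th percentile of the array. The percentile was taken over the 5858 probes well above background on all 12 arrays, because detection was under 50% on 9 arrays. Signals under a common floor of 0.0574 (-4.12 on the log2 scale), the highest of the arrays' lowest well-above-background signals, were raised to it before taking log2. This floor was chosen after the values had been seen, and 2 other floors were tried. Probes well above background on at least 6 arrays were tested, 16694 in all. Of these, 15425 had a gene name, for 11841 symbols. Over the array, 22951 probes were named by matching their accession to the gene table of assembly GRCm38.p6, 11480 kept the name in the file, and 6743 had none. Gene lists, tests, named-gene rules and most alternatives were fixed before the data were examined.

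Twin similarity was the mean over the 6 embryos of the root-mean-square log2 difference between the cells of an embryo. It was set against all 225 ways to pair the 6 cells within each experiment, in an exact one-sided permutation test. Probes were tested with limma 3.58.1: embryo as a factor with a moderated F test over the 4 embryo contrasts within experiments, cell number and its interaction with experiment with embryo as a fixed block, and experiment with embryo as a random block. The threshold was a Benjamini-Hochberg adjusted p under 0.05. Counts of probes over 1.5-fold apart in every twin pair, and the mean absolute correlation between twin difference profiles, were set against the same 225 pairings. Scores of gene lists with at least 5 tested genes were means of log2 values centred per gene within experiment. They were compared by re-pairing for embryos and by an exact two-sided test over 64 sign flips for cell number. For experiment, camera was run on the moderated t of each gene instead of these scores. It was used in its form for ranked statistics, with a preset correlation of 0.01. That form was used because camera takes no random block. Camera sets a list against the other genes, so its direction is relative to them and not to 0. R 4.3.3, numpy 2.4.6, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were also used.

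Named genes followed a rule. For embryos these were the 20 genes with the smallest adjusted p and up to 4 passing members of each list. For cell number and the interaction they were the 4 smallest unadjusted p, as no probe passed. For experiment they were the 10 highest and 10 lowest log2 differences among passing genes measured on all 12 arrays. For asymmetry and twin variance they were the 20 largest values among genes measured on all 12 arrays, with 2 members per list for the variance, and up to 4 examples per list elsewhere. Any member of the lists of other cells and sex chromosome transcripts could be named. A gene that the rule named for twin variance is not reported here. A gene was represented by its probe with the highest mean. Folds between embryos, and folds written as at least, set the mean of the brighter group against a mean in which each array of the dimmer group took the higher of its own lowest well-above-background signal and the probe's signal. Folds between experiments of probes measured on all 12 arrays come from the fit.

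Tests were also run on simulated data. Among 16694 probes, limma recovered 8 of 100 probes with a 2-fold and 35 of 100 with a 4-fold difference between embryos. It recovered 26 and 71 for cell number and 21 and 70 for experiment, and called 0, 6 and 11 unchanged probes. The pairing tests were run on 1000 simulated probes, independent and of equal spread. The test of twin similarity gave a p under 0.05 in 100% of 100 runs with an embryo effect and in 5% of runs without one. The test of shared twin differences gave one in 34% of 100 runs with a strong shared axis and in 7% of runs with no effect. Cells re-paired across embryos also carry such an axis. The embryo effect acted on every probe and was smaller than the twin spread. Real probes are correlated and held at a floor, so these shares are not the power in these data.

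Alternatives covered the floor, scaling, background correction by normexp with an offset of 50, quantile normalization, the deposited value table, the filter on dim probes, outlier spots, each cell and each embryo left out, blocks, moderation and the distance measure. Slide as a random block, planned for the embryo test, could not be estimated: its correlation was set to 0 because the embryo terms already encode the slides. The number of arrays limits the precision, and with 2 cells per embryo the spread is shared across embryos.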

Results

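The data are array profiles of 12 single blastomeres from 6 mouse embryos split at the 2-cell stage, with 2 cells from each embryo. Experiment 1 held pairs D, I and L and experiment 2 held pairs D, G and H, so each experiment had 3 embryos and 6 cells. The share of non-control spots well above background differed widely between arrays. In experiment 1 it was 22.1% and 38.7% in the cells of pair D, 37.1% and 33.7% in pair I, and 29.8% and 41.7% in pair L. In experiment 2 it was 78.8% and 64.3% in pair D, 31.2% and 52.8% in pair G, and 46.7% and 37.5% in pair H. Oocyte transcripts were among the best detected: 76.9 to 100% of the probes of the maternal list were well above background on each array, against 8.0 to 80.0% for markers of cumulus and granulosa cells.

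**Figure D1:**
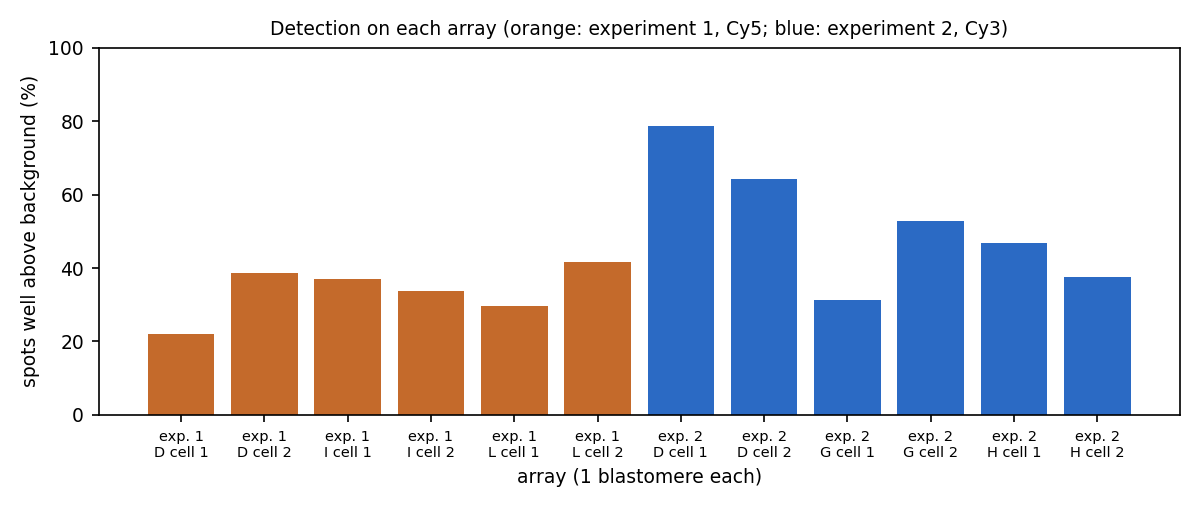
Share of non-control spots well above background (%) on each of the 12 arrays, 1 bar per blastomere. Cell 1 of pair D in experiment 2 reached 78.8%, and cell 1 of pair D in experiment 1 had 22.1%.

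The first question was whether the cells of an embryo resemble each other more than cells of different embryos. Over the 16694 tested probes, twins differed by 0.79 log2 units on average (root mean square; SD 0.14, n = 6 pairs). Cells of different embryos in the same experiment differed by 0.96 (SD 0.16, n = 24 pairs). The closest twins were those of pair D (0.63) and pair H (0.64) in experiment 2, and the most distant were those of pair L in experiment 1 (1.01). The true pairing had the lowest mean distance of all ways to pair the cells within experiments, 0.79 against a mean of 0.93, and the exact one-sided permutation p of 0.0044 is the smallest these pairings can give. The nearest cell was the twin for 6 of 12 cells, where chance gives 20%. In each experiment alone the true pairing also had the lowest mean of 15 (exact p = 0.0667, the smallest that 15 pairings allow). Centring the values by cell number as a replicate block left the exact p at 0.0044, which adds no support. Such centring draws cells of different number together, and twins always differ in number. Twins always shared a slide. Re-paired within the 2 slides that held 2 embryos, the true pairing was the lowest of 9, at an exact p of 0.111, the smallest possible there.

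**Figure D2:**
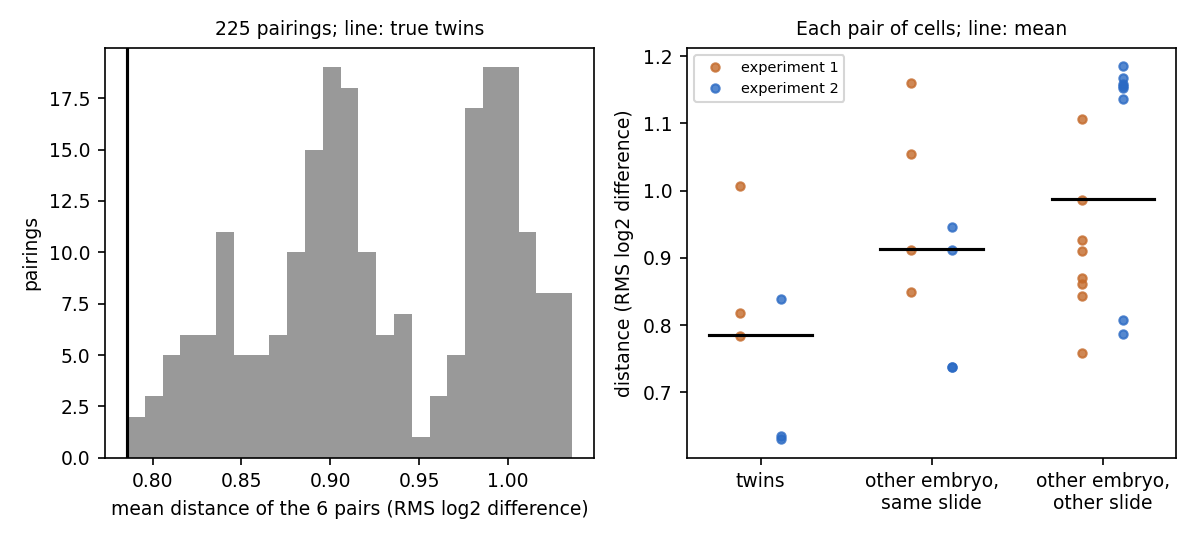
Left, number of pairings by the mean root-mean-square log2 difference of the 6 pairs, for all pairings of cells within experiments, with the true twins as a line at 0.79. Right, the distance (log2) of each pair of cells by kind, with the mean as a line: 0.79 for twins, 0.91 for cells of different embryos on the same slide and 0.99 on other slides, in that order 0.99 and 0.91 in experiment 1 and 0.83 and 1.07 in experiment 2.

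The next question was which transcripts were alike in twins and different between embryos. Pair I of experiment 1 stood apart in several abundant transcripts. Its cells were at similar levels, which the test favours. Pair I lay farthest from the others of its experiment for 19 of the 234 passing probes. In experiment 1 alone limma called 0 probes (1515 at an unadjusted p under 0.05), so none of these genes passed there. Trim61, of the tripartite motif family, was 24.0-fold lower in pair I than in pair L (0.67 against 5.25 log2 units, SD 0.52 and 0.05, n = 2; adjusted p = 0.0260 in limma). The oocyte transcript E330034G19Rik was 10.7-fold lower, the uncharacterised A530032D15Rik 11.3-fold lower than in pair D, and the probe the file names Tcra, after the T cell receptor alpha gene, 38.0-fold lower than in pair L. C130026I21Rik, not well above background in either cell of pair I, was at least 109-fold lower there than in pair D. Its neighbour Sp110, a nuclear body protein in the genome activation list, was 2.78-fold lower than in pair L (adjusted p = 0.0371 in limma).

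Other transcripts set other embryos apart. Phf11a was not well above background in pair D of experiment 1 and was at least 16.1-fold higher in pair I (adjusted p = 0.0193 in limma). Bop1, needed for ribosome assembly, was at least 14.3-fold lower in pair L of experiment 1 than in pair D, where 1 of 2 arrays of pair L measured it. In experiment 2, Stx7, a syntaxin of the endosome, was at least 10.2-fold lower in pair G than in pair D, measured on 1 of 2 arrays of pair G. The kinesin Kifc2 was 10.5-fold lower in pair H than in pair D, and Mtf2, a partner of the Polycomb complex, was 5.34-fold lower in pair H than in pair G. Uhrf2, a ubiquitin ligase that binds modified DNA, was 4.36-fold higher in pair I than in pair D of experiment 1. The transcription factor genes Tbx2 and Foxo3 and the genes Dnahc8, 1700016K19Rik, LOC381484, 4933403O03Rik, Gpr162, Evx1 and Il1rapl2 also passed, the last 3 of them at the floor in all 3 embryos of experiment 1. Of the 6 embryos, pair D of experiment 2, with the highest detection, lay farthest from the others of its experiment for 91 passing probes, and it was higher for 89 of them.

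By list, 2 of 18 tested genes of embryonic genome activation passed (Sp110 and the deubiquitinase Usp17la, 3.85-fold higher in pair H than in pair G of experiment 2), and 2 of them adjusted over the list alone. Of 41 maternal oocyte genes 2 passed, E330034G19Rik and Nlrp14, and 9 adjusted over the list alone. Nlrp14 was 3.11-fold higher in pair H than in pair G. Of 53 cytoskeleton genes 2 passed and 6 adjusted over the list alone. Myl9, a myosin light chain of smooth muscle, was 32.2-fold lower in pair L than in pair I of experiment 1, and the tubulin Tubb3 was 2.61-fold higher in pair L than in pair I. The trophectoderm factor Tfap2a, the replication helicase subunit Mcm5 and the histone deacetylase Hdac1 were the passing members of the trophectoderm, S phase and chromatin lists (1 gene of 15, 29 and 26; 3, 5 and 2 adjusted over the list alone). In the remaining lists no gene passed limma's test over all genes by its representative probe, though a second, dim probe of Krt7 did (adjusted p = 0.0497 in limma). Adjusted over the list alone, 3 proteasome, 4 cumulus and 2 sex chromosome genes passed. The scores of the lists passed in 0 of 16 lists (exact re-pairing test), with 4 at an unadjusted p under 0.05: maternal oocyte, pluripotency and chromatin (adjusted p = 0.119 each) and cumulus (adjusted p = 0.124). With normexp 8 lists passed, and 2 and 3 lists passed without cell 1 and without cell 2 of pair I of experiment 1.

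In all, 234 of 16694 probes passed limma's test between embryos, and 4983 had an unadjusted p under 0.05. For 74.8% of the passing probes both cells of at least 1 embryo lay at the floor, against 60.2% of the other tested probes. The count depended on single cells, the floor, the filter and the experiment, and its probes on the scaling. In experiment 1 alone limma called 0 (1515 at an unadjusted p under 0.05), against 784 in experiment 2 alone. Quantile normalization gave 235, with 83 of the 234 and 15 of the 20 genes named first among them. The 75th percentile of all probes gave 333, with 30 of the 234 and 6 of those 20 genes. The count was 1 with a lower common floor or the deposited values, where 1 of those 20 genes passed. It was 4356 with a floor per array and 6629 with normexp, and 19 of those 20 genes passed under each. Without cell 1 or cell 2 of pair H of experiment 2 it was 0 in limma, with 3286 and 3264 at an unadjusted p under 0.05. It was 32, 112 and 110 without cell 1 of pair D of experiment 1, cell 2 of that pair and cell 1 of pair D of experiment 2. It was 116 and 144 without cells 1 and 2 of pair I, 3875 and 1833 without cells 1 and 2 of pair L, and 1143 and 1464 without those of pair G. With cell number as a replicate block it was 0 (limma, 5409 at an unadjusted p under 0.05). Within the 2 slides that held 2 embryos it was 14, and 0 within each (limma, 1406 and 1507 at an unadjusted p under 0.05). Trim61 and Tcra passed under 22 of 29 alternatives and Sp110 under 13 of 29, while Mcm5 and Tubb3 passed under 10 of 29, Nlrp14 under 11 of 29 and Tfap2a under 11 of 28. A second probe of Tcra, C130026I21Rik, E330034G19Rik and Uhrf2, and 2 further probes of Mtf2, did not pass.

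**Figure D3:**
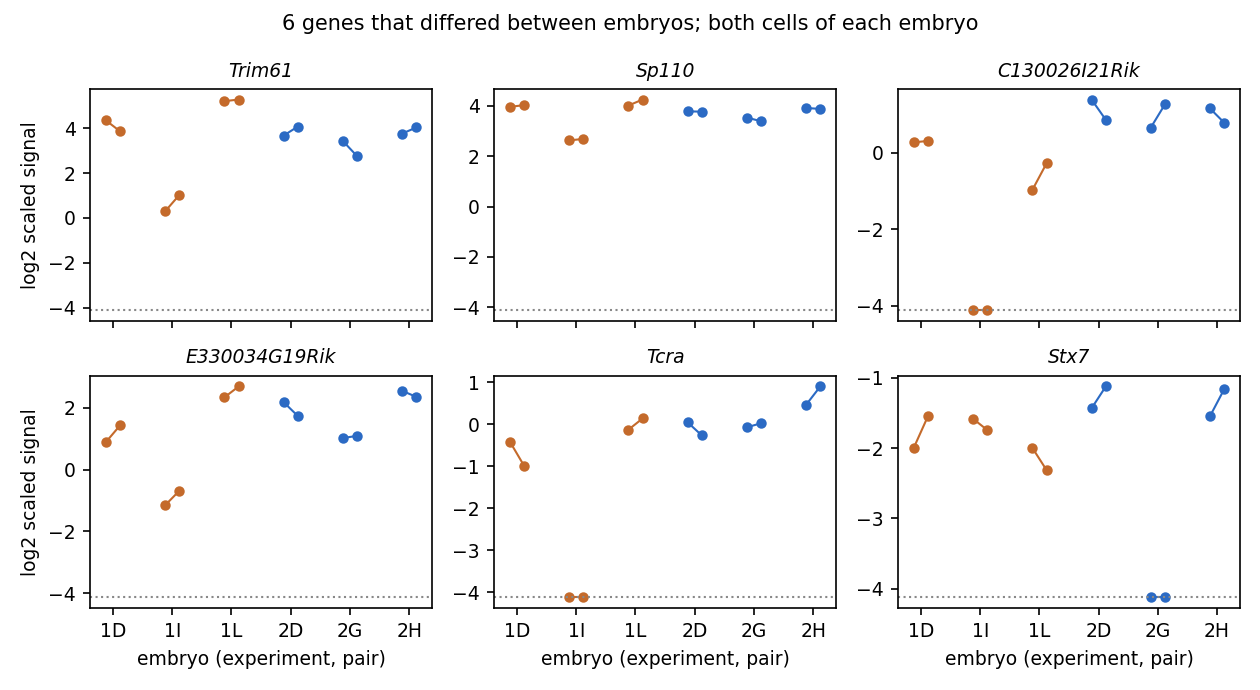
Log2 scaled signal of 6 genes that differed between embryos, with the 2 cells of each embryo joined by a line, orange for experiment 1 and blue for experiment 2, and the floor of -4.12 dotted. Both cells of pair I of experiment 1 lie lowest for Trim61, Sp110, C130026I21Rik, E330034G19Rik and Tcra, and both cells of pair G of experiment 2 for Stx7.

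Whether the numbering of the cells carries a signal was asked next. The smallest unadjusted p belonged to Tube1, which encodes epsilon tubulin and averaged 1.08 log2 units less in cell 2 (lower in 6 of 6 pairs), and to Kbtbd11 (1.25 less, 6 of 6 pairs). Stxbp5 and Plxna2, a semaphorin receptor, averaged 1.19 and 1.63 log2 units more in cell 2 in 6 of 6 pairs. None of them passed (adjusted p = 0.674 in limma for each). Limma called 0 probes between cell 2 and cell 1, with 737 of 16694 at an unadjusted p under 0.05. That latter count was 1742 with the deposited values, 1486 with a lower common floor and 1051 with a floor per array, where limma called 0 probes as well. The scores of embryonic genome activation and of the cumulus and granulosa list were higher in cell 2 in 6 of 6 pairs, by 0.19 (SD 0.19) and 0.45 (SD 0.45) log2 units. Their exact p of 0.0313 is the smallest that 64 sign flips give, and the adjusted exact p was 0.250. Camera with a preset correlation instead called 3 lists: ribosomal proteins and oxidative phosphorylation lower and cumulus higher in cell 2. With an estimated correlation none was called (adjusted p = 0.713 for ribosomal proteins and cumulus and 0.906 for oxidative phosphorylation). The ribosomal protein score was lower in cell 2 in every pair of experiment 1 and higher in every pair of experiment 2. The oxidative phosphorylation score was higher in cell 2 in 3 of 6 pairs.

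The cell contrast was also compared between the experiments. Hscb, an iron-sulfur cluster chaperone, Ramac, a cap methyltransferase subunit, and Hpcal1, a calcium sensor, had a lower cell 2 to cell 1 difference in experiment 2 (by 1.98, 1.67 and 2.98 log2 units). Cfd, complement factor D, had a higher one (by 2.88). None passed (adjusted p = 0.912 in limma for each). Limma called 0 probes for this difference, with 879 at an unadjusted p under 0.05.

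The order of twins may carry no meaning, so differences were also counted without it. Rtbdn, which encodes retbindin, differed by at least 1.12 log2 units between the twins of every embryo, higher in cell 2 in 4 of 6. Sestd1 (0.98 or more), Prkg1, a cyclic GMP-dependent kinase, BC004004, and the proteasome subunit Psmd8 (0.89 or more) came next. The list went on with Zfp768, 1810006K21Rik, Ltbp4, Unc45a, Ggps1, Taok1, Ostf1, Lztr1, Skp2, Ddx31, Brip1, Cdc42se1, Nme3, Dus3l and Capza2, down to 0.71. In all, 138 probes were over 1.5-fold apart in all 6 pairs, 66 of them measured on all 12 arrays. Re-paired cells gave a mean of 300.0 and a range of 135 to 562 (exact one-sided p = 0.996), so twins exceeded the threshold at fewer probes than re-paired cells. Only 4 of the 138 went the same way in every pair, where chance gives 4.31: Snap91, Tube1, Slc35b2 and Kbtbd11, all lower in cell 2. These 4 were named after their values were seen.

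A shared pattern of twin differences was looked for next. Across probes, which are not independent replicates, the twin differences of pair L of experiment 1 and pair G of experiment 2 had the highest correlation (0.259). The mean absolute correlation between the twin difference profiles was 0.0694, against 0.140 over re-paired cells (exact one-sided p = 0.960). Re-paired cells share differences between embryos, and the test recovered few simulated axes, so this p cannot exclude a shared axis.

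The transcripts that varied most between twins for their brightness were measured on all 12 arrays as well. The keratin Krt18 came first, with a twin variance 13.0 times the trend over all tested probes at its mean signal over the 12 arrays. That mean joined 3.23 log2 units in experiment 1 and -2.34 in experiment 2, so the trend there need not match either experiment. Pigt and the ribosomal and oxidative phosphorylation lists, lower in experiment 2, share this limit. Glg1, Yif1b, Ctps2, Zfp414, Mrps34, Pigt, Fau, Cst3, Cfp, Elob, Slc35c1, Nif3l1, Hps4, Socs3, Ecm1, Ptpn1, Phgdh and Taldo1 followed, at 9.90 to 7.23 times. Among ribosomal proteins, Rpl38 (6.56 times) and Rplp0 (6.44) varied most, and the list's median was 1.76 times. Oxidative phosphorylation, led by Ndufb10 and Uqcrq, had a like median (1.77), as did trophectoderm (1.75), where Atp1b1 followed Krt18. The ribosomal and oxidative phosphorylation scores differed most in pair I of experiment 1, by -1.09 and -1.11 log2 units in cell 2, where the oviduct score differed by -1.83 and a probe of Hba-a1 stood at -3.56 against 0.25 in cell 1. The genome activation list had a median of 0.504, although Zscan4c, a marker of genome activation, reached 3.11 times and Hspa1a 1.63. Maternal oocyte genes had a median of 0.714, with Ybx2 at 5.03 and Npm2 at 1.76. Over 5858 probes the median twin SD was 0.49 log2 units, 3.69 times the median SD of replicate spots within arrays (0.13), which holds no noise of amplification, labelling or hybridisation.

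Experiment 2 was then compared with experiment 1, a contrast that coincides with a change of dye, scan and slides. Among genes measured on all 12 arrays, Ptprz1, a receptor phosphatase, was 166-fold lower in experiment 2. Its difference was -7.37 ± 0.42 log2 units (SE, n = 6 cells of 3 embryos each, with embryo as a random block). Galectin 1 (Lgals1) was 117-fold, Crip1 53.1-fold, Krt18 47.7-fold, Tagln 31.7-fold, vimentin (Vim) 26.7-fold and apolipoprotein E (Apoe) 24.4-fold lower. Pigt, a subunit of the GPI transamidase, Lrrc58 and Mrpl33 were 42.1-fold, 27.3-fold and 23.7-fold lower (adjusted p in limma from 5.7e-06 for Ptprz1 to 0.00621 for Krt18 and Apoe). Snapc3, of the complex that drives small nuclear RNA genes, was 9.02-fold higher in experiment 2, the RNA polymerase III subunit Polr3k 8.54-fold, the poly(A) polymerase Papola 5.61-fold and the nucleoporin Nup35 5.64-fold higher. Gnat1 (7.45-fold), Zfp7 (6.98-fold), Tiam2 (6.45-fold), Fbxw11 (6.16-fold), Nfs1 (5.77-fold) and Gm16367 (5.70-fold) completed the 10 highest (adjusted p up to 0.0115 in limma). For Lrrc58, Zfp7 and Papola 1 of 3 probes passed, and for Polr3k 1 of 2.

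Of the 16 lists, 8 passed camera's test. A split of the embryos that mixed the experiments called as many lists at the preset correlation, so the count alone does not tell the experiments apart. Embryonic genome activation was higher in experiment 2 (4 of 18 genes passing, 4 higher; 7 adjusted over the list alone), as with Tcstv1 (4.31-fold), Tcstv3 (2.74-fold) and Tdpoz1 (3.63-fold). G2 and mitosis genes rose (8 of 25, 8 higher; 14 adjusted over the list alone), among them Cenpe (3.27-fold), Aurka (2.39-fold), Plk1 (2.43-fold) and cyclin B1 (Ccnb1, 1.96-fold). The adjusted p of limma's camera was 5.7e-05 and 1.5e-07 with a preset correlation, and 0.0208 and 0.0111 with an estimated correlation. Cytoskeleton genes were lower, with 11 of 53 falling and 1 rising (15 adjusted over the list alone), led by Vim, the non-muscle myosin Myh9 (6.30-fold), cofilin (Cfl1, 7.70-fold) and beta actin (Actb, 8.02-fold; adjusted camera p = 5.7e-05 in limma, and 0.0252 with an estimated correlation).

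S phase genes were higher, with 6 of 29 rising (7 adjusted over the list alone), such as Gmnn, an inhibitor of replication licensing (3.74-fold), and Orc6 (2.82-fold), at an adjusted p of 0.0837 with an estimated correlation in limma. RNA processing genes were higher, with 16 of 77 rising (22 adjusted over the list alone), such as Magoh (2.44-fold) and Rbm8a (3.95-fold), at an adjusted p of 0.191 with an estimated correlation in limma. Ribosomal protein genes were lower, with 24 of 82 falling and 1 rising (42 adjusted over the list alone), such as Rpl28 (5.23-fold) and Rplp2 (3.11-fold), at an adjusted p of 0.213 with an estimated correlation in limma. Oxidative phosphorylation genes were lower, with 11 of 72 falling and 1 rising (20 adjusted over the list alone), such as Ndufb7 (18.9-fold) and Uqcr11 (13.1-fold), at an adjusted p of 0.300 with an estimated correlation in limma. Maternal oocyte genes did not pass as a list, while Zar1, Ybx2, Khdc3 and Tle6 fell (4 of 41, and 4 adjusted over the list alone). With normexp this list passed in the other direction, as camera ranked it above the other genes (adjusted p = 0.00975 in limma). The median of all tested probes was -0.76 log2 units there, so this does not show a rise in experiment 2. The trophectoderm list, lower in experiment 2 relative to the other genes, passed with the 75th percentile of all probes, quantile normalization and the deposited table (adjusted p = 0.0244, 0.0295 and 0.0389 in limma). Krt8 and Krt18 fell in the trophectoderm list, Uhrf1 and Ehmt2 in the chromatin list, Trp53 and Junb in the stress list and Psmb3 in the proteasome list, and Zfp42 rose in the pluripotency list and Crb3 in the polarity list. Adjusted over the list alone, 2 genes passed in each of the trophectoderm and pluripotency lists, 1 in polarity, 4 in chromatin, 8 in stress and none in the proteasome list. For the maternal, trophectoderm and stress lists the median was above 0 and the mean below it. For the chromatin list both were above 0. Camera ranked these lists below the other genes without passing them, where the median of all genes was 0.19 log2 units.

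In all, 1353 probes passed limma's test between the experiments, 660 higher and 693 lower in experiment 2, and the median of all tested probes was 0.19 log2 units higher. That median moved by -0.19 with the 75th percentile of all probes, -0.15 with quantile normalization, 0.22 with the deposited table, -0.95 with normexp and -0.31 with a floor per array. It fell below 0 with normexp (-0.76), with a floor per array (-0.11), without the 3 arrays with the highest detection (-0.14) and without both cells of pair D of experiment 2 (-0.04). The split depended on the scaling: the 75th percentile of all probes gave 22 higher and 151 lower, normexp 56 and 373, a floor per array 94 and 274, and a lower common floor 296 and 494. Quantile normalization gave 1019 higher and 858 lower, the deposited values 593 and 498, and the omission of pair H of experiment 2 800 and 583. Without cell 1 of pair L of experiment 1 the count was 796. Without both cells of pair D or I of experiment 1, or of pair G of experiment 2, it was 650, 868 and 591. Means of twins gave 823, and cell number as a replicate block 1192.

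Among markers of other cells, 4 of the oviduct list and Lyz2 were high in experiment 1. Ovgp1, the oviduct glycoprotein, was well above background on 6 of 6 arrays of experiment 1 and on 1 of 6 in experiment 2, where it was at least 293-fold lower (adjusted p = 0.000483 in limma). A second probe of Ovgp1, well above background on 1 array of experiment 1 and 3 of experiment 2, lay at the floor on all 12 and was not tested. The epithelial markers Wfdc2, Krt7 and Krt19 were at least 149-fold, 86.4-fold and 77.3-fold lower in experiment 2, with 2, 3 and 3 of 6 arrays measuring them. A second probe of Krt7 differed by 0.46 log2 units and did not pass. The oviduct list was lower in experiment 2 with a median of -4.60 log2 units (4 of 7 tested genes falling, and 4 adjusted over the list alone; adjusted camera p = 4.5e-08 in limma, and 0.0118 with an estimated correlation). Tppp3, Foxj1 and Pax8, its other members, differed by -0.94, -0.21 and 0.54 log2 units and did not pass. Their means in experiment 1 were -2.64, -3.28 and -3.64 log2 units, near the floor, so a fall like that of the 4 passing genes could not have been seen. Among blood markers Lyz2, the lysozyme of macrophages, was at least 901-fold lower in experiment 2 (4 of 6 arrays), though its second, dim probe differed by 0.01 log2 units, while Lyz1 and the globins Hba-a1 and Hbb-bt did not pass (1 of 4 tested genes falling, 2 adjusted over the list alone). The 4 genes were too few for camera, which called the blood list lower in experiment 2 with 8 genes, with detection on at least 2 arrays (adjusted p = 0.0123 in limma) and with no filter (adjusted p = 0.00798). The 6 tested genes of the cumulus and granulosa list lay near the floor in experiment 1, with means of -4.00 to -2.75 log2 units, so that a fall like that of the oviduct list could not have been seen (median 0.32 log2 units, 0 of 6 passing in limma and 0 adjusted over the list alone). Of the sperm and sex chromosome lists 3 genes each were tested and none passed. Krt8, Krt18, Vim and Actb, which many cell types express, were lower in experiment 2 together with these markers. The cytoskeleton, ribosomal protein and oxidative phosphorylation lists were lower in the same contrast. Whether their falls share a source with the markers of other cells was not tested.

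**Figure D4:**
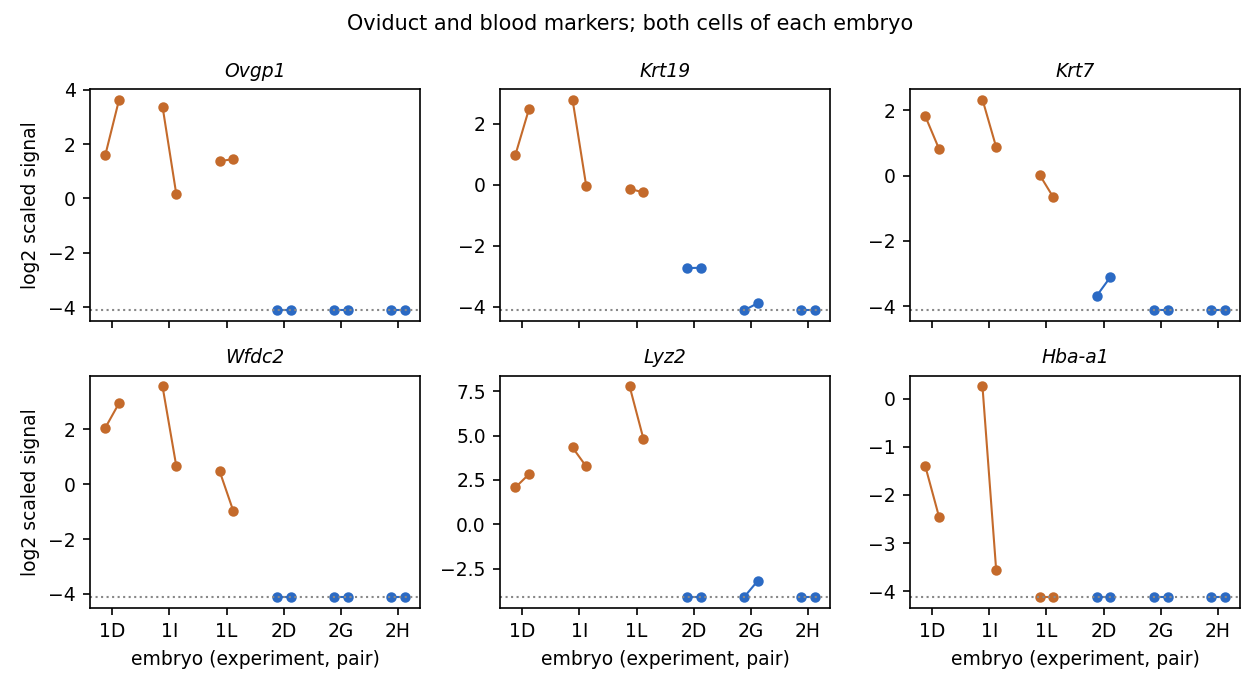
Log2 scaled signal of oviduct (Ovgp1, Krt19, Krt7, Wfdc2) and blood (Lyz2, Hba-a1) markers, with the 2 cells of each embryo joined by a line, orange for experiment 1 and blue for experiment 2, and the floor of -4.12 dotted. Ovgp1 and Wfdc2 lie at the floor in the 6 cells of experiment 2 and above it in the 6 cells of experiment 1.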

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

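The tests of a shared slide, of detection and of values at the floor, and all 3 tests of the oviduct transcripts, were chosen after the result was seen, as were the comparisons within slides.

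Ovgp1, Wfdc2, Krt7 and Krt19 were high in the 6 cells of experiment 1 and near or at the floor in experiment 2. A dye or protocol difference acting on all probes of a brightness was argued against: the oviduct list's median difference was -4.60 log2 units, where 10000 random lists of like signal lay between -0.83 and 0.84 in their central 95%. A lower scaled signal of dim probes in experiment 2 was argued against too: the list's median minus the lower bound (-0.95) of random lists matched on signal in experiment 1 was -3.65 log2 units, a test that replaced one on the cumulus list, whose genes lay near the floor already and had no room to fall. RNA of oviduct cells or fluid may have come along with the embryos of experiment 1. The mean pairwise correlation of the 7 oviduct genes over its 6 cells was 0.319 (permutation p = 0.0067), though these cells come from 3 embryos. Single correlations ran from 0.94 for Krt19 with Wfdc2 to -0.687 for Krt7 with Pax8. Against matched random lists of genes over the same cells the resampling p was 0.0169, a comparison added after the first p was seen. Dye effects specific to single probes stay open, because dye and experiment cannot be told apart, and a biological difference between the embryos of the experiments was not tested.

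Cells of an embryo were closer to each other than re-paired cells. Different detection of dim probes was argued against only as calls above background: over the 5858 probes measured on all 12 arrays the exact p was again 0.0044, the smallest possible. Such probes could still be raised to the common floor, as a probe of Nr5a1 was in cell 1 of pairs G and H of experiment 2. Values at the floor that twins share therefore stay open as a part of the cause. Oviduct RNA carried by embryos of experiment 1 stays open as a part of the cause: in experiment 2, where those transcripts were near the floor, the true pairing was the lowest of 15, but its exact p of 0.0667 is the smallest these allow. A slide shared by the twins cannot be told apart from a shared embryo, since the exact p of 0.1111 within slides is the smallest that 9 pairings allow, with ratios of twin to other distances of 0.919 and 0.885, while the twins of pair L (1.01 against 0.99) and of pair G (0.84 against 0.83) were no closer than other cells of their slides, and cells of different embryos were closer on a shared slide in experiment 2 (0.83 against 1.07) but not in experiment 1 (0.99 against 0.91). A common origin of the cells, which the design names, is consistent with the values but was not separated from the slide.

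Of the 234 probes that differed between embryos, the drawn pairings of the cells gave as many in 1 of 100 splits, the real one, with 22 probes as the highest of the others. This argues against chance alone for the main values, whose floor was chosen after they had been seen. No splits were drawn with the lower common floor or the deposited values, where the real pairing gave 1 probe. None were drawn without a cell of pair H of experiment 2 either, where it gave 0. Chance stays open under those settings. Values at the floor may make twins look alike: in 74.8% of the passing probes both cells of an embryo lay at the floor, against 60.2% of the other probes, while 70 of the 234 were measured on all 12 arrays, and a fit to such probes alone passed 30, of which 26 were among the 234. A strain variant carried by an embryo cannot be told from other causes, with 1 neighbouring pair of genes passing together, C130026I21Rik and Sp110, where random draws gave a median of 1. The bound set before that result was seen, at or below the median, was met, but by no more than the spread of the draws; the rule that this spread must be exceeded was added once the value was known. A slide, or the detection on its arrays, cannot be told from an embryo for pair D of either experiment, which was alone on its slide. Pair D lay farthest from the others for 26 probes in experiment 1 and for 91 in experiment 2, where it was higher for 89. Fits within the 2 slides that held 2 embryos passed 14 probes together and 0 within each (limma, 1406 and 1507 at an unadjusted p under 0.05). Differences between the embryos themselves stay open as a biological explanation and were not tested apart from these.

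Single values far from the others of their experiment were found in 9 of 72 groups of 6 cells, where chance gives about 1 in 20 groups. That rate does not apply to the probes of Hbb-bt and Lyz2 below, since most other cells of their groups lay at the floor. The standard deviation of negative control spots was 3.75 in cell 2 of pair D of experiment 1 and 16.6 in cell 2 of pair G of experiment 2. In cell 2 of pair L of experiment 1 the scores of the chromatin list (0.42) and the cumulus list (1.15) lay above those of the other cells, and 1 probe of the globin gene Hbb-bt was at -3.43 log2 units. Another probe of Hbb-bt stood at -1.63 in cell 1 of pair I of experiment 1, and a further one at -3.82 in cell 2 of pair D of experiment 2. Lyz2 stood at -2.55 in cell 1 of pair L of experiment 1 by its dim probe and at -3.20 in cell 2 of pair G of experiment 2 by its bright one. Ribosomal protein scores were lower in cell 2 in the 3 pairs of experiment 1 and higher in the 3 pairs of experiment 2, a difference of 0.70 log2 units that was not tested. In the Cy3 channel of experiment 1, which no comparison used, up to 160 spots of an array were well above background.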

How the results depend on the processing

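The floors, the fits within slides and the omission of the 3 arrays with the highest detection were chosen after seeing the data. Of the values of summary results under alternatives, 247 kept their direction and side of the threshold or moved little, 73 moved and 3 were weaker; of those of single genes and lists, 3406 were the same, 514 weaker, 3 stronger, 29 moved and 24 reversed. The reversed ones were lists that did not pass between experiments as reported, of which maternal oocyte passed in the other direction with normexp. Camera's direction is relative to the other genes, and the median of all tested probes fell below 0 in some of these settings. That median was -0.76 log2 units with normexp, so a reversal need not be a rise in experiment 2. Adjusted p in limma was 0.842, 0.494, 0.00975 and 0.278 for maternal oocyte with a floor per array, quantile normalization, normexp and without the 3 arrays. It was 0.929, 0.953, 0.616 and 0.876 for chromatin with a floor per array, the 75th percentile of all probes, normexp and without the 3 arrays. It was 0.99, 0.951 and 0.648 for cumulus with quantile normalization, normexp and without the 3 arrays, and 0.869 for stress with normexp. For proteasome it was 0.901, 0.986 and 0.876 with detection on at least 2 arrays, no filter and without the 3 arrays, and for polarity 0.985 on all 12 arrays. With a cell or an embryo left out the adjusted p in limma ranged from 0.0857 to 0.994 for maternal oocyte, 0.569 to 0.94 for polarity, 0.512 to 0.965 for proteasome and 0.458 to 0.957 for cumulus. Where no cause is given, the cause was not tested. The number of probes that differed between embryos, 234, was 4356 with a floor per array, 1 with the lower common floor, 1 with the deposited table, 6629 with normexp, 3516 with detection on at least 2 arrays, 30 with detection on all 12 and 2752 with no filter. It was 68 without the 3 arrays, 0 with cell number as a replicate block, 0 in experiment 1 and 784 in experiment 2 alone, 14 within slides, and 0 and 0 within slides 2 and 4 (limma, 5409, 1515, 1406 and 1507 at an unadjusted p under 0.05 for the zeros), and 0 to 3875 with a cell or an embryo left out. With the 75th percentile of all probes it was 333, of which 30 were among the 234. Between experiments, 1353 probes became 368 and 790 with those floors, 173 with the 75th percentile of all probes, 429 with normexp and 823 with means of twins, and 591 to 1561 with a cell or an embryo left out. The exact p of twin similarity was 0.0667 in each experiment alone and 0.111 within slides, where fewer pairings allow no less, and 0.00444 to 0.04 with a cell or an embryo left out. It was 0.0178 with a Spearman distance, 0.0133 with the 75th percentile of all probes and with the deposited table. With normexp it was 0.00889, and 0.0222 with the lower common floor. Probes over 1.5-fold apart in all pairs, 138, were 260 at 1.4-fold, 12 at 2-fold, 4 in the same direction, 652 and 506 with those floors, 264 with the 75th percentile of all probes, 365 with the deposited table, 66 on all 12 arrays and 530 without the 3 arrays. They were 236 to 281 with 1 pair fewer, as fewer pairs must pass. List scores between embryos passed for 8 lists with normexp and 0 to 3 with cells or embryos left out, camera called 4 lists between experiments with an estimated correlation and 3 between cells with a preset one, and the median twin SD was 0.42 with normexp. Slide as a random block gave no estimate. Signal over background limits the dim lists, with 8.0% of the cumulus probes detected in the weakest arrays.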

Other observations

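The tests of the splits were fixed before the data were examined, and the values per cell below were chosen after they were seen.

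Zscan4c, a marker of embryonic genome activation, differed most between the twins of pair I in experiment 1, with a mean of -1.22 log2 units and an SD of 2.13 (n = 2), while both cells of pair H in experiment 2 were near 0.02 (SD 0.27). Lyz2 was highest in cell 1 of pair L (7.77), where Krt19, Krt7 and Wfdc2 were lower than in both cells of pair D. Among sperm transcripts the protamine gene Prm2 stood between the floor and -0.53. Of the sex chromosome transcripts, Sry and Zfy2 were highest in the cells of pair D of experiment 2, at -2.51 and -2.69 for Sry, where detection of all probes was highest.

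Other splits of the samples were counted for the remaining fits. All 32 of the 32 splits that swap cell numbers gave as many probes as the real one, which a real count of 0 in limma (737 at an unadjusted p under 0.05) fixes, so they decide nothing. Between experiments the real split gave 1353 probes and the highest other 0, 1 of 10 splits, too few for a share under 0.05. The cell contrast between experiments gave 0 in limma (879 at an unadjusted p under 0.05) in the real split and a highest other of 0, and its 10 of 10 splits decide nothing for the same reason. For the lists between experiments the real split gave 8 and the highest other 8, 2 of 10 splits. The remaining splits called from 1 to 6 lists, though each called 0 probes. The list count at the preset correlation therefore does not set the real split apart.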
